A study of Mus musculus with 11 samples.

How the data were processed

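The samples were mouse embryonic stem cells from a female CAST/129 hybrid background, profiled by transient transcriptome sequencing (TT-seq), in which newly made RNA takes up 4-thiouridine (4sU), is fragmented, biotinylated at the 4sU and pulled down. Per the labels' protocols, wild-type F121-9 cells, an established mouse embryonic stem cell line, received 30 nM of a non-targeting siRNA (siNT) or of an siRNA against Zc3h4 (siZC3H4). They were exposed to 500 µM 4sU for 20 minutes and harvested 47 hours after transfection. The tables held 3 siNT libraries (replicates 1, 2 and 3) and 2 siZC3H4 libraries (replicates 2 and 3), which the series' design text calls biological replicates. The labels do not say whether replicates came from separately grown cultures, so part of the spread between these samples, on which p-values draw, may be technical. The series also describes 3 DMSO and 3 dTAG-13 samples of cells carrying a degradable ZC3H4, which are not analysed here.

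Per the submitters' processing notes, the tools were cutadapt 1.14, STAR, featureCounts and DESeq2, and the genome builds were mm10 and dm6; the notes as used here give no order or settings. Libraries were made with a stranded total RNA kit, per the labels' protocols. The authors deposited 2 tables of depth-normalized signal, one of 5867 upstream antisense RNA (uaRNA) regions and one of 13088 genes counted over exons. Per the file headers the gene table gives a symbol, a gene type, a transcript length and coordinates. The uaRNA table names each region by its host gene's identifier and gives no coordinates, so positions quoted for a uaRNA are those of its host gene. Every uaRNA host was in the gene table, as a protein-coding gene.

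In both tables the deposited signal was a whole read count divided by 1 depth factor per library. The factors were 1, 1.15 and 1.172 for siNT replicates 1, 2 and 3, and 1.767 and 1.046 for siZC3H4 replicates 2 and 3, the same in both tables. With these factors 100% of values came out whole within a tolerance of 0.01 reads. How the authors obtained the factors is not given in the sources used here. The recovered exon reads were 14840637, 17563244 and 18479834 in the siNT libraries and 26548710 and 16173640 in the siZC3H4 libraries. The uaRNA reads were 996927, 1031703 and 1195995 against 2648683 and 1448879. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 5.08 or higher for each pair in the uaRNA table and 17.2 or higher in the gene table. All were therefore kept as separate samples.

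Tests were run on log2(deposited value + 1) with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, siZC3H4 minus siNT, with no block. A feature was tested if its mean over the 5 libraries was 10 or more, which kept 5124 uaRNAs and 12482 genes and left out 743 and 606. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. "Rose" and "fell" describe features past that threshold. Fold changes are on the log2(value + 1) scale, which understates changes of low features. Standard errors (SE) are limma's moderated ones, and levels are given as mean ± SD of depth-normalized reads. Moderated tests had 67.5 degrees of freedom for uaRNAs and 9.22 for genes. The p-values of single uaRNAs therefore rest largely on the spread that limma borrows from all uaRNAs.

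On simulated tables of the same sizes, with 200 features changed by known folds, limma recovered 93.9% of 4-fold, 47.8% of 2-fold and 10.4% of 1.5-fold changes among 5124 uaRNAs, with 6 false calls. Among 12482 genes it recovered 100% of 4-fold, 73.1% of 2-fold and 17.9% of 1.5-fold changes, with 5 false calls. The 200 simulated changes went both ways, while 3180 of 5124 uaRNAs rose in the data. Recovery after adjustment depends on the share changed, so the uaRNA figures do not give the recovery in the data. A simulated list of 30 genes raised 1.5-fold was called by camera, limma's gene-set test, and so were 2 of 100 unchanged lists at an unadjusted threshold of 0.05. Genes were simulated independently, so this does not show how often camera calls unchanged lists whose members vary together. The lists that camera called in the results had estimated correlations between 0.48 and 0.67.

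The uaRNA shift was the per-library difference between the median deviation of uaRNAs and that of genes, compared by a two-sided exact permutation test. With 3 libraries against 2 there are 10 splits and the smallest p is 0.1. Relations across uaRNAs and genes used Pearson and Spearman correlations with 100000 permutations and Fisher's exact test. Of the 24 gene lists, the 22 with more than 1 tested member were tested by camera with a preset correlation of 0.01, with an estimated correlation and fry beside it. Gene classes were compared by a permutation test of the difference of medians. It shuffles genes, which are not independent replicates, so its p does not measure the spread between libraries. The numbers of exons per gene are not in the tables, so only genes whose span equals their transcript length were set apart, as single-exon models (515 genes). In 6 genes the table gives a start above the end, and these were left out of groups based on position or span. RefSeq genes of GRCm38.p6 were used only for names of neighbouring genes and to find uaRNAs with another gene close upstream of the host start. Distances to neighbouring starts and ends used only the genes that the authors counted over exons.

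The main tests, gene lists and naming rule were fixed before the data were examined, and tests chosen later are named as such where they are given. The text names Zc3h4; the 10 largest rises and 10 largest falls of exon reads among genes past the threshold with a mean of 50 or more and no overlap between the groups' libraries, with the 5 largest each way among conventional symbols; per gene list up to 4 members past the threshold or else the member with the highest mean; and, by the same criteria, the 10 largest rises and 5 largest falls of uaRNAs and the 4 highest uaRNAs of naive pluripotency genes. Values of 1 uaRNA and 2 genes that this rule names are left out of the text and plots, while counts include them. Alternatives covered the pseudocount (0.5 and 5), the filter (none, or a mean of 50), the scaling (median of ratios, equal totals and TMM within a table), limma without the trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and leaving out each library. In the block fit siNT replicate 1 shares its number with no other library and drops out of the comparison. The p-values of that fit rest largely on the spread that limma borrows from all features. Thinning every library to the shallowest, and counts without features near an annotated opposite-strand start, were added after the data were seen. Sequence composition of the uaRNAs was not analysed here, since no genome sequence was at hand.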

Results

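Nascent RNA was measured in F121-9 mouse embryonic stem cells 47 hours after transfection with a non-targeting siRNA (siNT, n = 3) or an siRNA against Zc3h4 (siZC3H4, n = 2). ZC3H4 and WDR82 form the Restrictor complex, which attenuates transcription of noncoding RNA. Values are reads divided by the authors' depth factor for each library. Before that division, exon reads totalled between 14840637 and 26548710 per library. Reads of upstream antisense RNAs (uaRNAs), the short-lived transcripts that leave promoters in the direction opposite to the gene, totalled between 996927 and 2648683, also before division. The totals can include other RNAs, since the regions with the most reads, those of Ccdc107, Parp2 and Gtf3c6, have Rmrp, Rpph1 and Rnu3a in the 1 kb upstream of the host start. The 10 regions with the most reads took 23.8% to 27.0% of uaRNA reads in the siNT libraries and 11.2% to 17.3% in the libraries labelled siZC3H4.

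The siRNA target was examined first, as a planned check of the labels. Exon reads of Zc3h4 (ENSMUSG00000059273, chromosome 7, 16400500 to 16437696, mm10) were 3479 ± 125 (SD, n = 3) in the siNT libraries and 7002 ± 401 (SD, n = 2) in the libraries labelled siZC3H4. They rose 2.01-fold (log2 1.01 ± 0.11 SE, limma adjusted p = 0.0043). The siZC3H4 label would give a fall of the target's mature mRNA, while these reads come from newly made RNA. The rise therefore does not settle whether the labels are right. Each direction given here is drawn from libraries labelled siZC3H4. Nascent exon reads do not measure mature mRNA or protein, neither of which was measured here. The individual libraries held 3465, 3610 and 3363 reads against 7285 and 6718, so the groups did not overlap. Reads of the Zc3h4 uaRNA were 139 ± 33.4 and 149 ± 47.1 and did not pass the test (log2 0.09 ± 0.27 SE). They fell when the uaRNA table was scaled on itself by the median of ratios (log2 -0.80) or TMM (-0.78), scalings that centre the uaRNAs and so measure it against the other uaRNAs. Exon reads of Wdr82, the partner of ZC3H4 in the complex, were 8835 ± 691 and 9376 ± 846 and did not pass the test either (log2 0.09 ± 0.12 SE). The fold of Zc3h4 stayed between log2 0.95 and 1.07 whichever library was left out, but its limma adjusted p was 0.0549 without siNT replicate 1 and 0.0578 without siZC3H4 replicate 2.

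**Figure D1:**
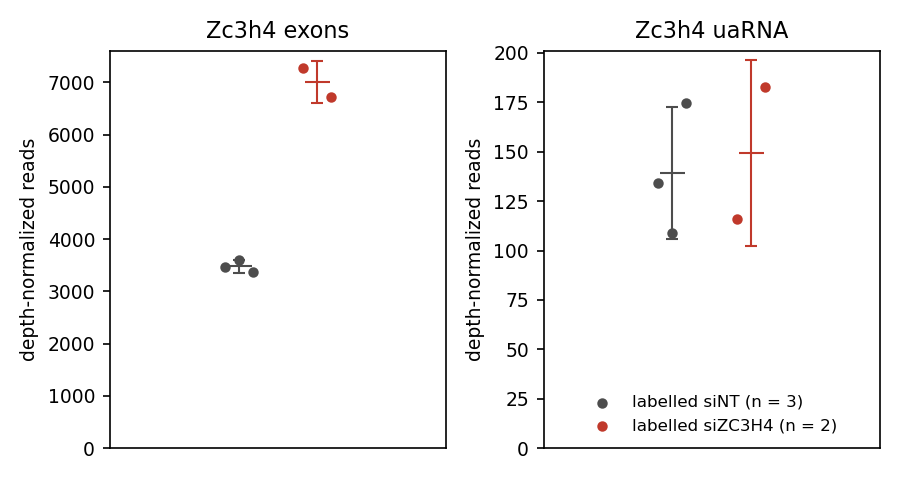
Depth-normalized reads over Zc3h4 exons (left) and in the Zc3h4 uaRNA region (right), on linear axes from 0; points are libraries, bars the mean and SD of 3 siNT libraries and 2 libraries labelled siZC3H4. Exon reads were 3363 to 3610 in the siNT libraries and 6718 to 7285 in the others, while the uaRNA values overlapped.

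Upstream antisense RNAs were compared to ask how promoter-divergent transcription differed between the groups. Of 5124 uaRNAs tested, 3180 (62.1%) rose in the libraries labelled siZC3H4, 58 (1.13%) fell and 1886 did not pass the test. The falls include the regions of Parp2 and Gtf3c6, where reads can come from Rpph1 and Rnu3a. Of the 58, 16 had another RefSeq gene in the 1 kb upstream of the host start, against 22.2% of all uaRNAs with a position. The median log2 fold change was 0.88 (interquartile range 0.46 to 1.31), a 1.84-fold difference, and 2183 uaRNAs rose at least 2-fold. The uaRNA of Mettl22, a protein methyltransferase gene, had the largest fold under the naming rule, from 10.5 ± 3.97 (SD, n = 3) to 129 ± 73.3 (SD, n = 2), a rise of 10.8-fold (log2 3.44 ± 0.39 SE, limma adjusted p = 8.35e-11). The uaRNAs of Btbd8 and of the zinc finger gene Zfp94 rose by log2 3.29 ± 0.31 and 3.23 ± 0.28.

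The uaRNA of Commd7 rose by log2 3.18 ± 0.38 SE, that of Washc1, a subunit of the WASH complex on endosomes, by 3.13 ± 0.31, and that of the kinase gene Pak4 by 3.09 ± 0.37. The uaRNA of Laptm5, a lysosomal membrane protein gene, rose by log2 2.98 ± 0.33 SE. The uaRNA of Egln2, an oxygen-dependent prolyl hydroxylase gene, rose by 2.92 ± 0.36, and that of Plxnb2, a semaphorin receptor gene, by 2.86 ± 0.29. These uaRNAs passed the limma test with each siNT library left out in turn, with p-values that rest largely on spread borrowed from all uaRNAs. Over the 10 largest rises log2 values were 2.37 or higher without siZC3H4 replicate 2 and 3.21 or higher without siZC3H4 replicate 3.

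At naive pluripotency genes, 17 of 21 tested uaRNAs rose and 0 fell, against 62.1% that rose over all uaRNAs. Their median log2 of 0.93 was not separated from the 0.88 of all uaRNAs (permutation p = 0.779, adjusted over 14 lists 0.877, a test chosen after the data were seen). The uaRNA of Pou5f1, which encodes OCT4, rose from 851 ± 15.9 to 1628 ± 220 (log2 0.93 ± 0.20 SE). Those of Dppa5a, Tfcp2l1 and Tbx3 rose by log2 1.16 ± 0.21, 0.97 ± 0.21 and 0.78 ± 0.21. These 4 calls were lost when the uaRNA table was scaled on itself by the median of ratios or TMM, where the Tbx3 uaRNA turned to -0.12 and -0.09. Both scalings centre the uaRNAs, so a uaRNA near their median of 0.88 must lose its call there. The exon reads of the same genes did not pass the test, with log2 values of -0.08 for Pou5f1, -0.27 for Dppa5a, -0.34 for Tfcp2l1 and 0.23 for Tbx3.

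The largest falls among uaRNAs were smaller than the largest rises. The uaRNA of Setd6, a lysine methyltransferase gene, fell from 446 ± 103 to 194 ± 86.1 (log2 -1.24 ± 0.25 SE, limma adjusted p = 2.51e-05). The uaRNA of Pycard, which encodes the inflammasome adaptor ASC, fell from 830.5 ± 172 to 366 ± 159 (log2 -1.23 ± 0.23 SE). Those of B3gnt9, Abraxas2 and Ifitm5 changed by log2 -1.10 ± 0.23, -0.97 ± 0.27 and -0.95 ± 0.28, and the call for Ifitm5 was lost without siZC3H4 replicate 2 (log2 -0.55, limma adjusted p = 0.179).

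These counts rest on the authors' depth factors, which are the same in both tables. When the uaRNA table was scaled on itself, which moved its median to 0.00 (median of ratios), 0.02 (TMM) or 0.32 (equal totals), 527, 548 and 1257 uaRNAs rose and 600, 573 and 319 fell, where 3180 rose and 58 fell at the authors' scaling. At that scaling 1840 rose and 16 fell without siZC3H4 replicate 2, and the number that fell was 34, 88 and 32 without siNT replicates 1, 2 and 3.

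**Figure D2:**
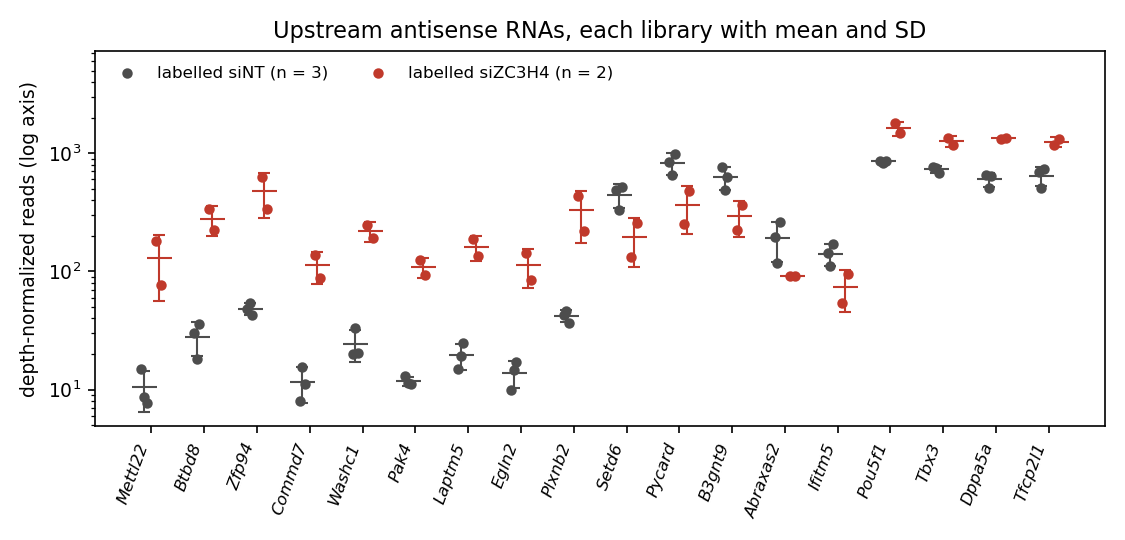
Depth-normalized reads of 18 named uaRNAs, labelled by host gene, on a log axis; points are libraries, bars the mean and SD of 3 siNT libraries and 2 libraries labelled siZC3H4. The first 9 lay higher in both libraries labelled siZC3H4, the next 5 lower, and the last 4 are naive pluripotency genes, whose uaRNAs lay higher at the authors' scaling. The Tbx3 uaRNA lay at log2 -0.12 and -0.09 when its table was scaled on itself by the median of ratios or TMM, which centre the uaRNAs.

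The shift of uaRNAs was then set against genes within each library. Relative to genes, the median uaRNA lay at log2 -0.21, -0.44 and -0.33 in siNT replicates 1, 2 and 3, and at 0.66 and 0.37 in siZC3H4 replicates 2 and 3. The groups differed by log2 0.85, or 1.80-fold, against a pooled SD of 0.15. The exact permutation test gave a two-sided p of 0.1, the smallest that 3 libraries against 2 allow. Of the uaRNAs, 73.7% were higher in both libraries labelled siZC3H4 than in every siNT library and 2.11% lower, where chance gives 10% each way. Of the genes, 19.5% were higher and 12.8% lower by that criterion.

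**Figure D3:**
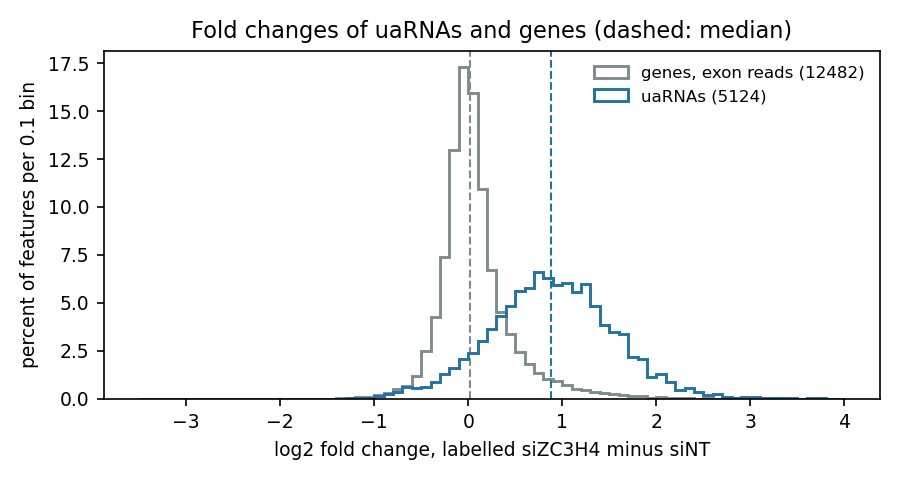
Distribution of log2 fold changes, libraries labelled siZC3H4 minus siNT, for 5124 uaRNAs and 12482 genes, as the percent of features per bin of 0.1; dashed lines mark the medians of 0.88 and 0.01. The uaRNA distribution lies to the right of the gene distribution.

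Exon reads were compared gene by gene between the same libraries. Of 12482 genes tested, 277 (2.22%) rose in the libraries labelled siZC3H4, 18 (0.144%) fell and 12187 did not pass the test, and the median log2 fold change was 0.01. With the replicate number as a block, 1530 rose and 830 fell. In that fit siNT replicate 1 drops out of the comparison, and p-values rest largely on the spread that limma borrows from all genes. Without siNT replicate 1 and with no block, 2 rose and 0 fell. Dglucy, a D-glutamate cyclase gene (ENSMUSG00000021185, chromosome 12, 100779095 to 100872354), rose 8.31-fold, from 109 ± 26.5 (SD, n = 3) to 900 ± 72.8 (SD, n = 2; log2 3.05 ± 0.22 SE, limma adjusted p = 9.69e-04). The lncRNA Gm11532 (chromosome 11, 97020508 to 97026142) rose from 202 ± 36.1 to 1560 ± 369 (log2 2.94 ± 0.21 SE).

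Other large rises fell on genes with low reads in the siNT libraries. Tcam1 rose by log2 2.57 ± 0.31 SE, from 26.5 ± 8.82 to 158 ± 18.2. The kinase-like gene Stkld1 rose 5.67-fold, from 22.3 ± 2.81 to 133.5 ± 40.1, and the homeobox gene Nkx2-9 rose 5.66-fold, from 23.6 ± 7.38 to 135.5 ± 25.3. The lncRNAs 9330104G04Rik, Gm10535 and Tnfsf13os rose by log2 2.48 ± 0.30, 2.33 ± 0.35 and 2.32 ± 0.31, and the transcribed pseudogene C920006O11Rik by 2.33 ± 0.19; reads of a pseudogene can be shared with its parent gene. Lefty1, an inhibitor of NODAL signalling, rose from a higher level, 2691 ± 73.5 to 5143 ± 143 (log2 0.93 ± 0.11 SE, limma adjusted p = 0.00534). Its limma adjusted p was 0.0555 without siNT replicate 1 and 0.0578 without siZC3H4 replicate 2.

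Genes that fell included Stra8, which is needed for entry into meiosis, from 175 ± 111 to 26.7 ± 8.18 (log2 -2.47 ± 0.51 SE, limma adjusted p = 0.0418). The siNT libraries spread widely for Stra8, with 291, 69.6 and 164 reads. Lsmem1 fell from 89.1 ± 18.1 to 25.8 ± 2.80 (log2 -1.74 ± 0.28 SE). The histone genes H2bu2 and H2aw, which lie near each other on chromosome 11, fell by log2 values of -1.33 ± 0.24 and -1.03 ± 0.16. Gp5, a platelet glycoprotein gene, changed by log2 -1.18 ± 0.25 SE and the atypical cadherin gene Celsr3 by -1.05 ± 0.20 SE. B4galnt4, Fam162a, Trim35 and Bricd5 fell by smaller amounts, with log2 values of -0.96, -0.95, -0.94 and -0.90.

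The number of genes past the limma threshold depended on single libraries. It was 2 higher and 0 lower without siNT replicate 1, 165 and 11 without siNT replicate 2, 676 and 138 without siNT replicate 3, 10 and 0 without siZC3H4 replicate 2, and 80 and 3 without siZC3H4 replicate 3. Of the 10 largest rises 8 lost the call without siNT replicate 1 and 7 without siZC3H4 replicate 2. Over all 10 the limma adjusted p ranged up to 0.0640 and 0.128 in these, and log2 values were 1.96 or higher. Of the 10 largest falls 10 lost it without siNT replicate 1, 6 without siNT replicate 2, 10 without siZC3H4 replicate 2 and 9 without siZC3H4 replicate 3, with log2 values of -0.78 or lower.

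**Figure D4:**
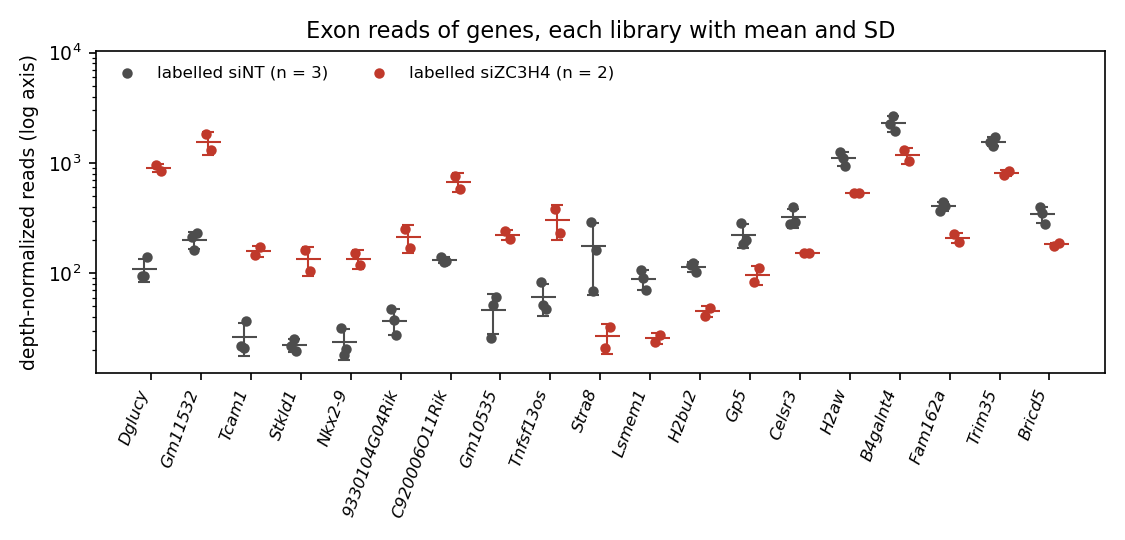
Depth-normalized exon reads of 19 named genes on a log axis; points are libraries, bars the mean and SD of 3 siNT libraries and 2 libraries labelled siZC3H4. The first 9 genes rose and the last 10 fell.

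Each uaRNA was paired with its own sense gene to ask whether both changed together. Among 5106 pairs, 3174 uaRNAs rose, and of their genes 30 rose, 1 fell and 3143 (99.0%) did not pass the test. Mettl22 exon reads were 598 ± 52.7 and 532 ± 44.0 (log2 -0.17 ± 0.15 SE) and did not pass the test. For Zfp94 and Btbd8 the exon values were log2 0.83 ± 0.20 SE and 0.84 ± 0.27 SE, with limma adjusted p of 0.0724 and 0.168. Across pairs, which are not independent replicates, Pearson's r was 0.0684 (permutation p = 1e-05, the smallest that the permutations can give) and Spearman's rho 0.0493 (permutation p = 3.8e-04). Differences between siNT libraries alone gave r from 0.153 to 0.222. Genes rose in 0.945% of pairs with a uaRNA that rose and in 27 of the 1932 other pairs (Fisher's exact test, odds ratio 0.673, p = 0.169).

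Long noncoding RNAs were set against protein-coding genes as the first of the gene classes. In the libraries labelled siZC3H4, 86 of 771 lncRNAs (11.2%) rose and 1 fell, against 188 rises (1.62%) and 17 falls among 11595 protein-coding genes. Their median log2 fold changes were 0.42 and 0.01, a difference of 0.41 (permutation p = 1e-05, the smallest possible, and 2e-05 adjusted over 4 class comparisons). The permutation was across genes, which are not independent replicates, so this p does not measure the spread between libraries. With each library left out in turn the difference lay between 0.38 and 0.46. Gm11532, 9330104G04Rik, Gm10535 and Tnfsf13os were among these lncRNAs, while Snhg1, a snoRNA host gene, had 19030 ± 3407 and 18460 ± 2821 reads and did not pass the test. All lncRNAs were also set against protein-coding genes with a mean between the lower and upper quartile of lncRNA means. The difference of medians was log2 0.32 (permutation p = 1e-05) and the odds ratio for a rise 4.27 (Fisher's exact test, p = 4.78e-17). The lncRNAs were not restricted to that range, so level was matched only roughly.

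Of 57 snRNA genes tested 0 rose and 0 fell in the limma test. Their median log2 fold change was -0.27 against 0.01 for protein-coding genes, a difference that was not tested. Single-exon protein-coding genes had a median of -0.05 against 0.01 for 11215 multi-exon genes, with 3 rises and 4 falls among 374. Their difference of -0.06 had a permutation p of 4e-05, and without siNT replicate 1 it was -0.02 with a p of 0.21. The shortest and longest quartiles of gene span differed by log2 0.02, which turned to -0.07 without siZC3H4 replicate 2.

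Gene lists fixed in advance were tested with camera over 22 lists with more than 1 tested member. Replication-dependent histone genes, whose transcripts are made in S phase, were lower as a group in the libraries labelled siZC3H4, with 27 of 28 members below 0 and a median log2 of -0.32 (camera adjusted p = 2.85e-10; adjusted p = 0.991 with an estimated correlation). That median was -0.19 without siNT replicate 1. Of these H2bc7 fell, from 2071 ± 124 to 1386 ± 29.5 (log2 -0.58 ± 0.12 SE, limma adjusted p = 0.0415), a call lost without each library other than siNT replicate 3 (log2 from -0.60 to -0.55), and 8 fell when adjusted over the list alone. Targets of p53 were higher as a group, with 17 of 20 above 0 and a median of 0.32 (camera adjusted p = 0.00118; adjusted p = 0.991 with an estimated correlation), though 0 passed the limma test singly or adjusted over the list alone. Sesn2 had the most reads of them, 8616 ± 2301 and 9946 ± 2176. Pmaip1 and Plk2, chosen after their values were seen, had fold values of 2.21 and 1.75 without passing the test, and Cdkn1a and Mdm2, also chosen then, had log2 -0.10 ± 0.17 and 0.30 ± 0.20. Genes of the integrated stress response were lower as a group (17 of 22 below 0, median -0.16, camera adjusted p = 0.0143, and 0.991 with an estimated correlation), with Atf4, its central transcription factor, at log2 0.05 ± 0.19. That median was -0.13 without siNT replicate 1, 0.0031 without siNT replicate 3 and 0.08 without siZC3H4 replicate 2, with camera adjusted p of 0.0536, 0.572 and 0.873. The fry test called 0 lists.

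Markers of cell identity gave few single calls. In the naive pluripotency list 0 of 25 genes passed the test, and the highest, Tfcp2l1, had 28440 ± 3632 and 22590 ± 5020 exon reads, passing only with the replicate number as a block (limma adjusted p = 0.0440). In the formative and primed epiblast list 12 of 16 genes lay above 0 with a median of 0.25 (camera adjusted p = 0.127), among them Etv5 at log2 0.27 ± 0.13 SE. Of the mesoderm and primitive streak list Lefty1 rose, and 2 of 8 rose when adjusted over the list alone. Of the endoderm list 0 of 10 passed in limma. Lama1, a laminin gene, had the most reads (log2 -0.54 ± 0.13 SE, limma adjusted p = 0.0724), and it was the 1 member that fell when adjusted over the list alone. Lama1 also fell with DESeq2 (adjusted p = 0.0171), with the block (1.46e-06) and without siNT replicate 3 (0.0178), while its adjusted p was 0.0740 with edgeR and between 0.114 and 0.580 without each of the other libraries. In neural ectoderm (8 tested) Tubb3 had log2 0.57 ± 0.21 SE, in trophoblast (4 tested) Tfap2c had -0.01 ± 0.15 SE and in the fibroblast or feeder list (6 tested) Fn1 had -0.10 ± 0.12 SE, and no member of the 3 lists passed, though Tubb3 did with the block (limma adjusted p = 2.97e-08). Of the two-cell-like list 3 genes were in the table and 1 was tested, Eif1a, at log2 0.10 ± 0.23 SE. Of 13 mitochondrially encoded mRNAs 0 were in the table.

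The machinery of RNA synthesis and decay also gave few calls. Zc3h4 was the 1 gene of 5 that rose in the Restrictor and PNUTS-PP1 list. Among 14 Integrator subunits, which act in early termination, 0 passed the test, and Ints3 had 3593 ± 687 and 5469 ± 964 reads (log2 0.61 ± 0.18 SE, limma adjusted p = 0.129). Ints3 passed with DESeq2 (adjusted p = 0.0470) and with the replicate number as a block (limma adjusted p = 1.04e-09), a fit in which siNT replicate 1 drops out. None of 23 genes of the nuclear exosome and its adaptors passed, nor of 22 cleavage and polyadenylation genes, 13 U1 snRNP and Sm genes or 23 pausing and elongation factors. The most abundant members of the exosome, cleavage and U1 lists were Exosc10 (log2 0.01 ± 0.12 SE), Wdr33 (-0.13 ± 0.15 SE) and Snrnp70 (-0.18 ± 0.11 SE). No member passed among 25 immediate early genes (Ier2 at log2 -0.35 ± 0.18 SE, past the threshold with the block at 0.00548), 14 heat shock genes (Hsp90ab1 at 0.09 ± 0.13 SE) or 7 interferon response genes (Irf1 at -0.15 ± 0.12 SE). The same held for 46 intron-poor genes (H2ax at -0.27 ± 0.13 SE), 34 ribosomal protein genes (median 0.07) and 27 genes of the noncoding and host gene list (median 0.03). Over the 20 lists in which limma called 0 members, 41 of 360 tested entries had an unadjusted limma p under 0.05, which is no excess. Of all 12482 genes tested, 1367 were higher and 548 lower at that unadjusted threshold. In those 20 lists edgeR called 0 entries and DESeq2 called 6. Camera gave adjusted p of 0.123 or higher for every list other than the 3 named above.

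**Figure D5:**
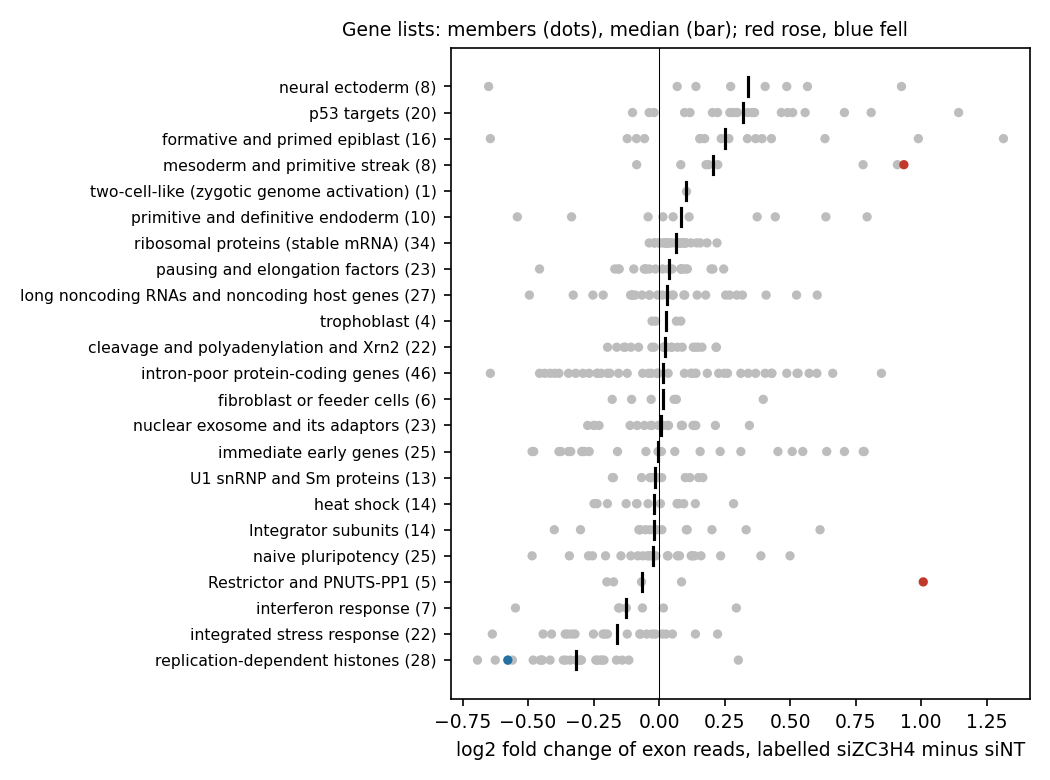
Log2 fold changes of exon reads, libraries labelled siZC3H4 minus siNT, for the tested members of 23 gene lists (numbers in brackets); grey dots did not pass the limma test, red rose, blue fell, and bars mark medians. The histone list has the lowest median, -0.32.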

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

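Thinning every library to the shallowest, and counts without features near an annotated opposite-strand start, were chosen after the data were seen, while the other alternatives were planned. Over 62 named features there were 1054 values under alternatives. Of these 964 kept their side of the threshold, 78 no longer passed, 10 newly passed and 2 were counted as reversed. Among the 964, values near log2 0 could still change sign. Both values counted as reversed were the Tbx3 uaRNA, at log2 -0.12 with the median of ratios and -0.095 with TMM of the uaRNA table. The Zc3h4 uaRNA, counted as newly passed, also changed sign, from log2 0.09 to -0.80 and -0.78 under the same scalings.

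With the uaRNA table scaled on itself, 527 uaRNAs rose and 600 fell (median of ratios), 1257 and 319 (equal totals) or 548 and 573 (TMM). The shift against genes was 9.05e-05 with each table on its own median of ratios. The median of ratios and TMM centre the uaRNAs (median log2 0.00 and 0.02), so they cannot show a common change, while equal totals left a median of 0.32. When both tables were scaled by the exon-based one, the shift was 0.85. Without the mean-variance trend 32 uaRNAs fell; the cause was not tested. Pseudocounts, filters, edgeR, DESeq2 and thinning gave between 2170 and 3258 rises, the lowest with a mean of 50 or more.

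For genes, DESeq2 called 537 higher and 97 lower, and 29 fell with the median of ratios; the cause was not tested. Without genes that have an opposite-strand start within 50 kb, 94 rose and 4 fell, from fewer genes tested. With the replicate number as a block 1530 rose and 830 fell. Only 2 numbers are shared between the groups, so siNT replicate 1 dropped out of that comparison. The p-values of the block fit rest largely on the spread that limma borrows from all genes. Libraries that share a number had correlated deviations over genes (0.528 and 0.618), but the labels do not state what a number shares. The 2 values are not independent, since the deviations of the 2 siZC3H4 libraries from their mean mirror each other. Of the gene lists, 0 were called with an estimated correlation and 0 by fry, against 3 with the preset one.

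Leaving out 1 library each time, uaRNA rises ranged from 1840 to 3097 and falls from 16 to 88, and gene rises from 2 to 676 and falls from 0 to 138. Where siZC3H4 was left with 1 library, that library was assumed to vary like the siNT libraries. The log2 fold of Zc3h4 ranged from 0.95 to 1.07, the shift from 0.71 to 0.99, the sense-pair correlation from 0.0653 to 0.114 and the lists called from 2 to 5. The lncRNA difference ranged from 0.38 to 0.46, the single-exon difference from -0.15 to -0.018 and the span difference from -0.072 to 0.14, reversed without siZC3H4 replicate 2. The integrated stress response list ranged from -0.43 to 0.076, reversed at 0.0031 without siNT replicate 3 and 0.076 without siZC3H4 replicate 2; the cause was not tested.

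The tests of sequence features and of exon number were not run. Thinned to the shallowest library, 3110 uaRNAs and 256 genes rose, so depth above that level had little effect on these counts. In simulated data limma recovered 47.8% of 2-fold changes among uaRNAs and 73.1% among genes.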

Other observations

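The tests of scaling, exchanged labels and a single mislabelled library for Zc3h4, of RefSeq neighbours for uaRNAs, and of uaRNAs over host gene lists, were chosen only after the result was seen. The wording of 1 preset test's pattern was narrowed after its result was seen and then put back as first written.

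The libraries labelled siZC3H4 had 2.01-fold more Zc3h4 nascent exon reads than siNT. A difference in scaling or depth is argued against, since the log2 fold change was still 0.97 at the lowest of 3 other scalings and thinning. A single mislabelled library is argued against by the uaRNAs, because the nearest libraries of the groups lay 0.58 apart on the log2 scale relative to genes, against a pooled SD of 0.15. An exchange of the labels of both groups cannot be told apart from labels that are right by the Zc3h4 reads. As labelled, 3180 uaRNAs rose and 58 fell at the authors' scaling, and 86 lncRNAs rose and 1 fell. That is the direction that loss of a complex attenuating noncoding transcription would give. Used to judge the labels it assumes the effect under study, so an exchange is not excluded. The median uaRNA log2 fold change was 0.88 as labelled and would change sign if the labels were exchanged, and no value here says which group had less ZC3H4 protein or mature mRNA. If the labels are right, transcription of Zc3h4 may have been higher where its product was depleted, which remains an untested hypothesis. No biological explanation was tested.

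Of 277 genes whose exon reads rose, a candidate explanation is antisense transcription from a neighbouring promoter that runs into the gene. Neighbours here are only genes that the authors counted over exons, so starts and ends of other annotated genes were not seen. With an opposite-strand start 1 to 10 kb upstream 26 of 980 genes rose (2.65%), against 127 of 7015 (1.81%) with none within 50 kb. The ratio of 1.465 had a 95% interval from 0.966 to 2.22, which reaches both no excess and the 2-fold excess set as the bound, so the explanation stays open. For protein-coding genes alone the ratio at that distance was 1.64 (1.03 to 2.63). Within 1 kb, a distance not set for the test, 85 of 1879 genes rose (4.52%, with a 95% interval of the ratio from 1.91 to 3.27), and from 0 to 10 kb the ratio was 2.15 (1.67 to 2.76). Of all genes that rose 54.15% had an opposite-strand start within 50 kb, against 43.77% of genes tested. Among named genes, Stkld1 starts 399 bp from such a start, 9330104G04Rik 520 bp, Tnfsf13os 2143 bp, Tcam1 3615 bp and Gm11532 3848 bp. Dglucy, C920006O11Rik, Gm10535 and Nkx2-9 lie 54029, 67322, 153051 and 617351 bp from the nearest among the counted genes, and a gene not counted may lie closer. Read-through from a gene upstream on the same strand over short distances is argued against as the main source. Genes with such an end within 10 kb rose at a ratio of 0.705 (95% interval 0.486 to 1.02), below the 2-fold bound. That ratio was 0.918 (0.605 to 1.39) for protein-coding genes and 0.302 (0.0966 to 0.942) for lncRNAs. With an end 10 to 50 kb upstream, a distance not set for the test, the ratio was 1.26 (0.974 to 1.64), and 1.39 (1.01 to 1.90) for protein-coding genes. Longer read-through thus stays open. Deeper sequencing of 1 library is argued against too, since 256 genes rose after thinning. No other explanation was tested.

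Of uaRNAs with a position, 1943 of 5120 did not rise. Low counts did not go with lower fold changes, because the lowest quartile of level lay 0.12 above the highest in median log2 (95% interval 0.05 to 0.17). Level was the mean over all libraries, siZC3H4 included, so the change itself helped set the filter and the quartiles. The comparison therefore does not settle this explanation. The share that rose was nevertheless 47.9% in the lowest quartile and 68.5% in the highest, so counts may limit single calls. Messenger RNA of an annotated divergent gene met the bound set for it. Only genes that the authors counted over exons were considered. The uaRNAs with such a gene start within 1 kb lay -0.55 from the others (95% interval -0.95 to -0.13), but they number 10, of which 6 did not rise. Within 5 kb, a distance looked at after the result was seen, 237 uaRNAs had such a start and 138 of them did not rise, with a difference of -0.45 (95% interval -0.58 to -0.31). This could reach a part of the 1943, and how large a part stays open because the size of the counted regions is not known. Another RefSeq gene in the 1 kb upstream is argued against as the main source, because 24.03% of the uaRNAs that did not rise had one, against 21.06% of those that rose. The uaRNAs with such a gene had a median log2 of 0.80 against 0.90 without, a difference of -0.10 (95% interval -0.15 to -0.05). No biological explanation was tested.

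Over host gene lists, 15 of 16 uaRNAs of p53 targets rose (median log2 1.38, permutation p = 0.0086, adjusted over 14 lists 0.0602) and 17 of 23 of ribosomal protein genes (median 1.31, permutation p = 0.0067, adjusted 0.0602), neither past the threshold.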
